A study of Mus musculus with 2 samples.

How the data were processed

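TCF12 ChIP-seq was measured in 2 biological replicates of the CH12.LX line, numbered by the biological replicate number in the labels, which form 1 group. The labels name a possible control experiment, and per the deposited descriptions of the files a control alignment entered each replicate's peak calls. The control reads themselves were not analysed here. The authors called peaks on each replicate alone and on both replicates pooled to give relaxed lists with background, and derived the optimal and conservative lists from these with the IDR step, which keeps peaks whose ranks repeat, all on mm10 per the file descriptions. The mm9 list was derived by the authors from the alignments of both replicates. The aligner, the peak caller and their versions are not given in the sources used here.

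Each peak has a start, an end, a summit offset and a signal value, and the signal is the authors' caller's own, deposited with no stated scaling. It was used only to describe and rank peaks within a list and to set the replicates side by side at the same peaks. The score of the optimal and conservative lists is the deposited scaled IDR score, and a score of at least 830 was taken as an IDR of 0.01 or less. Read depth is unknown, so no value has an interval for sequencing depth. Wilson intervals at the 95% level were computed for shares of peaks, and Poisson intervals for the ratio of densities, both for counting error only. Coordinates were written counting from 1.

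Which replicate peaks to compare, the gene lists, motifs, distances, tests and their alternatives were chosen before the data were examined, with the exceptions named here and in the closing section. Peaks counted as shared when they overlapped by at least 1 bp. Replicates were compared over as many of the strongest peaks of each as the conservative list holds, 35530, and chance overlap came from 100 circular shifts. Weak relaxed peaks, those of the pooled relaxed list that overlap no optimal peak, served as a background. Groups of summits were built with a linking distance of 12 kb and a minimum of 4 summits, and set against 100 shuffles.

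Genes on mm10 came from a RefSeq table of GRCm38.p6 that gives spans without strand, so the strand of each gene was taken from the GENCODE vM1 annotation by symbol on the same chromosome. Of 21631 protein-coding genes on chromosomes 1 to 19 and X, 20193 (93.4%) received a strand and were used. Promoters were within 1 kb of the annotated 5' end. Exons, introns and sequence needed the mm9 genome (NCBIM37 with GENCODE vM1), since an mm10 sequence and exon annotation were not used here. The intron share, the E-box ratio and the E-box share by signal were planned for the mm10 optimal peaks and were therefore computed on the mm9 list, which does not separate the replicates. No coordinate was converted between builds. Of the mm9 peaks, 23572 lie on chromosomes 1 to 19 and X.

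A motif counted as present when it lay wholly within 50 bp of the summit on either strand. Its share was divided by the mean share of windows centred 300 bp to either side, with an interval from 1000 bootstrap draws of peaks. The test was a two-sided exact McNemar test of each summit window against 1 of its flanks, left and right in alternation, with Benjamini-Hochberg adjustment over 32 motifs. For CAGCTG or CACCTG together no p is given, because it was too small to be resolved. Where a peak is said to hold an E-box or none with no sequence named, CAGCTG or CACCTG is meant. A peak without an E-box in this sense can hold another CANNTG. E-box shares of the strongest and weakest of 5 equal groups by signal were compared with 100000 permutations, counting absolute differences, while p-values for gene lists and for the correlation over chromosomes doubled the smaller tail. For each of 15 fixed gene lists, holding 362 genes of which 356 were measured, the share of genes with an optimal summit from 10 kb upstream of the 5' end to the 3' end was set against 10000 random gene lists of the same size, matched in 20 bins of gene span. P-values are two-sided with Benjamini-Hochberg adjustment over the lists, and a list was called at an adjusted p below 0.05. They compare genes within these libraries, not replicates, and expression was not used for matching. A peak can fall in the windows of several genes.

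The regions named are the 15 strongest optimal peaks and the 5 largest groups of summits. The genes named are all members with a peak of the list of E proteins, ID proteins and their partners, up to 5 members with the strongest peaks in every other list, the 5 genes with the most peaks and the genes nearest to named regions, with up to 4 members without a peak. A few of those genes were left out of the text for length, 1 item is not reported here, and the genes whose mm9 sequence is given were picked from them after their values were seen.

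Alternatives were a stricter IDR of 0.01, the conservative list, each replicate alone, merged peaks, a reciprocal overlap of 50%, summits within 100 bp, other numbers of peaks, promoter distances of 500 bp and 2.5 kb, motif windows of 25 and 100 bp, flanks 500 bp away, gene windows of 5 kb or the nearest 5' end within 100 kb, matching on weak relaxed peaks as well as span, and other settings for groups of summits. Peaks on unplaced sequences and on chromosome Y were left out of the comparisons by location, gene list and motif. The few on unplaced sequences stayed in the overlaps between replicates and between lists, and in the signal compared between replicates. The overlap, motif and gene list procedures were tested on simulated data. Of 20000 simulated peaks, a planted overlap of 69.9% was recovered as 69.9%. These peaks were spaced so that none overlapped another of its own list, so this checks the computation only. In 5000 simulated sequences, motifs at 24.0% were recovered as 23.9%, and 2% of 100 sets without planted motifs gave p below 0.05. The simulated bases were equally frequent at summit and flank, so this rate does not cover a base composition that differs between them. Of 200 simulated lists without an effect 6% gave p below 0.05, and 100% of 200 lists with a planted effect were called. Simulated genes were independent of each other, while neighbouring genes in the real lists can share a peak. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.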

Results

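TCF12, also called HEB, is an E protein, a basic helix-loop-helix transcription factor that pairs with other E proteins or with tissue-restricted partners and binds the E-box, a short DNA motif of the form CANNTG. Its binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in CH12.LX, an immortalised mouse line from a B-cell lymphoma. There was 1 group with 2 biological replicates and no treated or untreated counterpart, so the comparisons open to these data are between the replicates, between peaks and the rest of the genome, and between groups of genes. On the mm10 build the authors gave 35848 optimal peaks, kept after the irreproducible discovery rate (IDR) step, with a median width of 384 bp and a median signal of 35.0 in the caller's units. Their conservative list held 35530 peaks, and relaxed lists of 300000 peaks each were given for replicate 1, replicate 2 and the pooled data. A separate list of 23575 peaks was given on the mm9 build. The read depth behind the peaks is unknown, and every interval on a share covers counting error only, with neighbouring peaks treated as independent.

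The strongest optimal peak lay at the 5' end of Bag5, which encodes a co-chaperone of Hsp70, on mm10 chromosome 12 from 111712981 to 111713394. Its pooled signal was 496, from 264 in replicate 1 and 230 in replicate 2. The next, with a signal of 495, lay 108 bp upstream of Lrpprc, a mitochondrial RNA-binding protein gene, on chromosome 17 from 84790722 to 84791072. Most of the other peaks among the 15 strongest lay away from 5' ends. They included peaks inside Rab37 (signal 473), inside Arid3a (464), which encodes a DNA-binding activator of immunoglobulin heavy-chain transcription, and inside Gas7 (453), where the nearest 5' end was that of Rcvrn. A peak inside St6gal1, the sialyltransferase gene that makes ligands for CD22, reached 450. A peak 1.40 kb upstream of Cbfa2t3, a corepressor gene of the ETO family whose members bind E proteins, reached 417. Peaks 26.0 kb upstream of Ezh2, the histone H3 lysine methyltransferase gene of germinal centre B cells, and inside Il21r, the interleukin receptor gene, had signals of 407 and 396. The remaining 6 lay nearest to Adgrl2, Cdkn2aipnl, Ccdc188, Zfpm1, Cyfip2 and Fam174a, with signals from 370 to 452. All 15 had the highest possible IDR score of 1000.

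The 2 replicates marked largely the same places. Of the 35530 strongest peaks of replicate 1, 73.5% (95% Wilson interval 73.1 to 74.0) overlapped one of the 35530 strongest of replicate 2, against a mean of 1.08% (range 0.892 to 1.29) after 100 circular shifts along the chromosomes. All of the 1000 strongest peaks of each replicate overlapped one of the 35530 strongest of the other, while 68.8% of replicate 1's 1000 strongest overlapped one of replicate 2's 1000 strongest, and the median distance between nearest summits was 32 bp. Signal at the optimal peaks had a Spearman's rho between replicates of 0.697 and a Pearson's r of 0.710 for log2 signal, across the 34817 peaks found in both. These correlations are across peaks, which are not independent replicates, and the IDR step had already kept peaks whose ranks repeat, so they do not measure the replicates independently, and no p-value was computed. The signal was higher in replicate 1 at 85.7% of these peaks, with a median ratio of 1.66 (interquartile range 1.21 to 2.34). The pooled signal was 0.988 times the sum of the replicates' values at the median, and with no stated scaling to depth the ratio between replicates is not read as a difference in binding. Peaks found in the upper list of a single replicate lay near 5' ends less often, at 14.4% (13.7 to 15.1) for replicate 1 and 17.2% (16.4 to 17.9) for replicate 2, than those shared, at 33.4% and 33.0%. Peak strength was not held equal here, as only 15 and 20 of the 5000 strongest peaks of replicates 1 and 2 were not shared. Those few lay near 5' ends in 13.3% (3.74 to 37.9) of cases in replicate 1, against 35.8% of shared ones. In replicate 2 the direction turned, at 65% (43.3 to 81.9) against 40.3%.

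**Figure D1:**
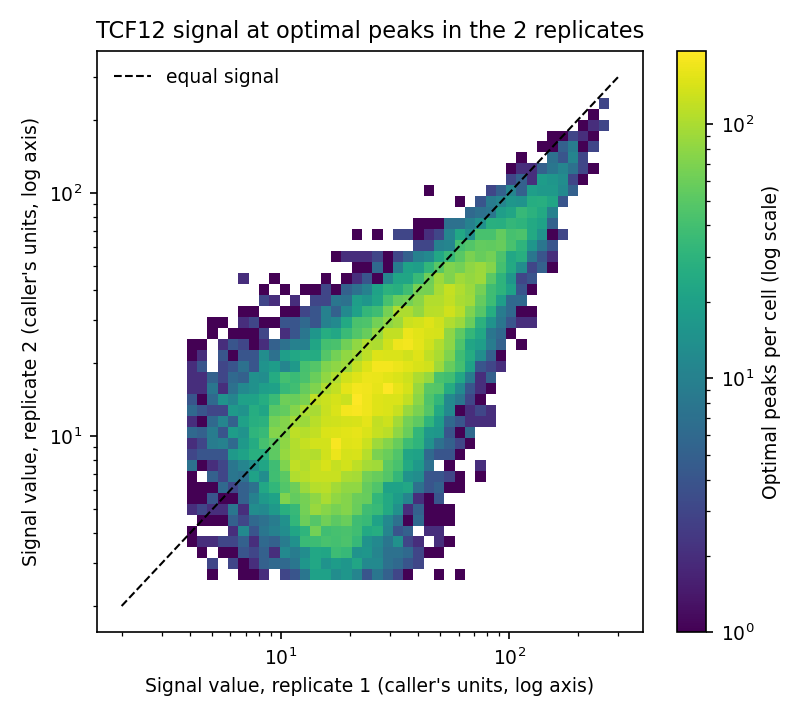
Signal of the optimal peaks in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), in the caller's units, with each cell coloured by its number of peaks on a log scale and a dashed line at equal signal. Most of the 34817 peaks lie below the line, with 85.7% higher in replicate 1, and Spearman's rho is 0.697.

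The optimal and conservative lists differed mainly in weak peaks. Of the optimal peaks, 83.6% (83.2 to 83.9) overlapped a conservative peak, and these had a median signal of 40.3. The other 5895 had a median signal of 19.9, and the 5415 conservative peaks with no optimal partner had 19.6.

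TCF12 peaks were concentrated at promoters, yet most lay elsewhere. Of the optimal summits, 28.9% (28.4 to 29.3) fell within 1 kb of the 5' end of a protein-coding gene, against 4.18% (4.10 to 4.26) of the weak relaxed peaks outside the optimal list and 1.46% of uniformly placed positions. The replicates gave 28.4% and 28.7% separately. A further 38.2% lay within gene bodies, below the 50.4% of weak peaks and close to the 36.8% of uniform positions, and 33.0% lay outside genes. The median distance to a 5' end was 10470 bp, and 50.6% of summits were more than 10 kb away. The promoter share was 38.5%, 36.3%, 25.8%, 19.5% and 24.2% in 5 equal groups from the strongest to the weakest signal. On mm9, where exons were annotated, 34.3% of 23572 summits lay at promoters, 30.4% (29.8 to 31.0) in introns, 4.83% in exons and 30.5% between genes. Random mm9 positions gave 1.59% for promoters, 35.4% for introns, 2.62% for exons and 60.4% between genes.

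The E-boxes CAGCTG and CACCTG were concentrated at the summits. Of the mm9 peaks, 31.0% (30.4 to 31.6) held at least 1 of them within 50 bp of the summit, against 12.2% in windows 300 bp away, a ratio of 2.55 (bootstrap interval 2.47 to 2.62). CAGCTG alone was found in 15.5% of peaks against 5.01% of flanks, a ratio of 3.08 (2.93 to 3.24; two-sided exact McNemar p = 3.58e-316, adjusted over 32 motifs 1.15e-314). CACCTG was found in 19.1% against 7.60%, a ratio of 2.52 (2.42 to 2.63; adjusted exact p = 3.01e-287). CATCTG and CACGTG followed with ratios of 1.76 and 2.10 (adjusted exact p = 4.21e-82 and 7.58e-31). The E-boxes CAATTG, CAAGTG and CAAATG were rarer at summits than in flanks, at 0.650, 0.865 and 0.887 times the flank share (adjusted exact p = 9.30e-07, 7.93e-05 and 0.0123). CACATG and CAACTG passed the threshold with ratios of only 1.13 and 1.05, and lost it with flanks 500 bp away (adjusted exact p = 0.469 and 0.628). The control palindrome CGATCG had a ratio of 1.08 (adjusted exact p = 0.226), but passed with windows of 25 bp (1.38, adjusted p = 0.0335) and with flanks 500 bp away (1.41, adjusted p = 0.00370), so ratios of 1.41 or less lie within the range of the control.

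The bases next to CAGCTG also differed between summits and flanks. ACAGCTGC made up 20.1% (18.9 to 21.3) of the 4219 CAGCTG sites at summits and 10.5% of the 2464 sites in flanks, 1.92 times as much. TCAGCTGA went the other way, at 2.13% of summit sites and 4.26% of flank sites. CAGCTG or CACCTG lay within 50 bp of the summit in 8 of the 15 strongest mm9 peaks, and in the strongest mm9 peak of 35 of 83 named genes. Those of Arid3a, Pax5, Ikzf3, Cd79b, Nfkb1 and Il10 held none. The mm9 peak upstream of Cbfa2t3, on chromosome 8 from 125224374 to 125224963, held CACCTG at 125224592 to 125224597 in the plus-strand context CTGGCTTGCACCTGTGGGGCCC. A peak about 9.5 kb upstream of Tcf3, the gene of the E proteins E12 and E47, lay between genes on mm9 chromosome 10 from 79905822 to 79906072. Its summit window held the reverse complement of CACCTG in GGGCCCCGCAGGTGTCTGGGGA, at 79905926 to 79905931. An intron of Lef1, a gene active in early B cells, held CAGCTG in GCCTGCCACAGCTGTTTGCTTA at mm9 chromosome 3, 130857642 to 130857647. An intron of Mef2b, a transcription factor gene of germinal centre B cells, held 2 E-boxes within 50 bp of the summit of its strongest peak, the nearer in CCTGGGAGCAGGTGATGAAACC at mm9 chromosome 8, 72682584 to 72682589.

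Promoter peaks seldom held either of the main E-boxes, CAGCTG and CACCTG. CAGCTG or CACCTG lay at the summit of 14.4% (13.7 to 15.2) of promoter peaks, against 35.7% (32.9 to 38.5) in exons, 40.7% (39.6 to 41.9) in introns and 39.1% (38.0 to 40.3) between genes. In promoters this was 1.23 times the flank share, and elsewhere 3.19 times, and the odds ratio of an E-box in promoters against elsewhere was 0.257. CACCTG was about as frequent at promoter summits as in their flanks, with a ratio of 0.991 against 3.33 elsewhere, while CAGCTG had 1.69 in promoters and 3.69 elsewhere. The E-box CACGTG had 2.27 in promoters and 1.959 elsewhere. Strong peaks outside promoters held E-boxes most often, at 54.1% in the strongest of 5 equal groups by signal and 33.4% in the weakest. Over all peaks the strongest group exceeded the weakest by 9.74 percentage points, 38.9% against 29.2% (two-sided permutation p = 1e-05 from absolute differences, the smallest that 100000 permutations can give in that way). The groups between held 28.2%, 29.0% and 29.5% from stronger to weaker, so over all peaks only the strongest group stood apart and the share did not rise steadily. Among the peaks of these groups that lay outside promoters, the share fell at each step with weaker signal. It was 54.1%, 39.9%, 38.1%, 34.7% and 33.4%. Promoter peaks, which seldom held an E-box, made up 38.1%, 43.4%, 35.7%, 28.9% and 25.5% of the groups in the same order. With the 5 groups formed again among peaks outside promoters alone, the difference was 20.3 points (permutation p = 1e-05, again the smallest possible), and with groups formed among promoter peaks the direction turned, at -3.09 points (permutation p = 0.0187).

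**Figure D2:**
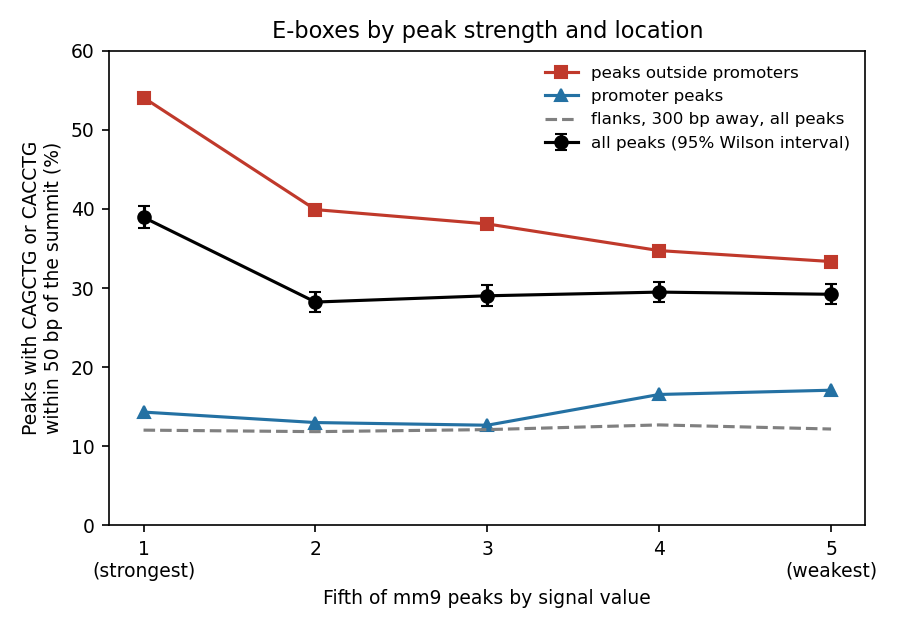
Percentage of mm9 peaks with CAGCTG or CACCTG within 50 bp of the summit (vertical) in 5 equal groups of signal from strongest to weakest (horizontal), for all peaks, peaks outside promoters, peaks in promoters and the flanking windows. Outside promoters the share is 54.1% in the strongest group and 33.4% in the weakest, while in promoters it stays between 12.7% and 17.1%.

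Several motifs other than E-boxes were also more frequent at the summits, and others were not. Outside promoters, the sites of EBF1, the factor that specifies the B lineage, were 6.35 times as frequent as in flanks, the octamer bound by OCT proteins 5.81 times, NF-kappaB sites 5.60 times, the PU.1 type of ETS site 4.76 times, AP-1 sites 4.75 times and RUNX sites 4.31 times. The AP-1-IRF composite element, bound by BATF with IRF4, had the highest ratio over all peaks, 18.8 (9.86 to 46.0), but occurred in only 75 peaks. CTCF sites, which mark chromatin boundaries, had a ratio of 16 in 248 peaks. In promoter peaks the ETS site CCGGAAGT lay in 6.86% against 0.526% of flanks, 13.1 times as often (6.23 times elsewhere). CREB sites were 8.72 times as frequent in promoters and 7.22 times elsewhere, SP/KLF sites 1.88 and 1.97 times, and YY1 sites 5.69 and 0.968 times. GATA, TCF/LEF and FOXO sites were rarer at summits, with ratios over all peaks of 0.412, 0.644 and 0.687, and the site of the Ikaros family (IKZF) did not pass the threshold, with a ratio of 0.868 (adjusted exact p = 0.138), but passed as lower with windows of 100 bp (0.000281) and flanks 500 bp away (5.69e-05). NFY sites had a ratio of 0.803 over all peaks, 1.11 in promoters and 0.673 elsewhere. In all, 22 of the 32 motifs were more frequent at summits and 7 less frequent at an adjusted p below 0.05. The summit windows had a median GC content of 56.4%. Base composition was matched only for CAGCTG or CACCTG together, so the ratios of single motifs, higher or lower, are not corrected for it.

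**Figure D3:**
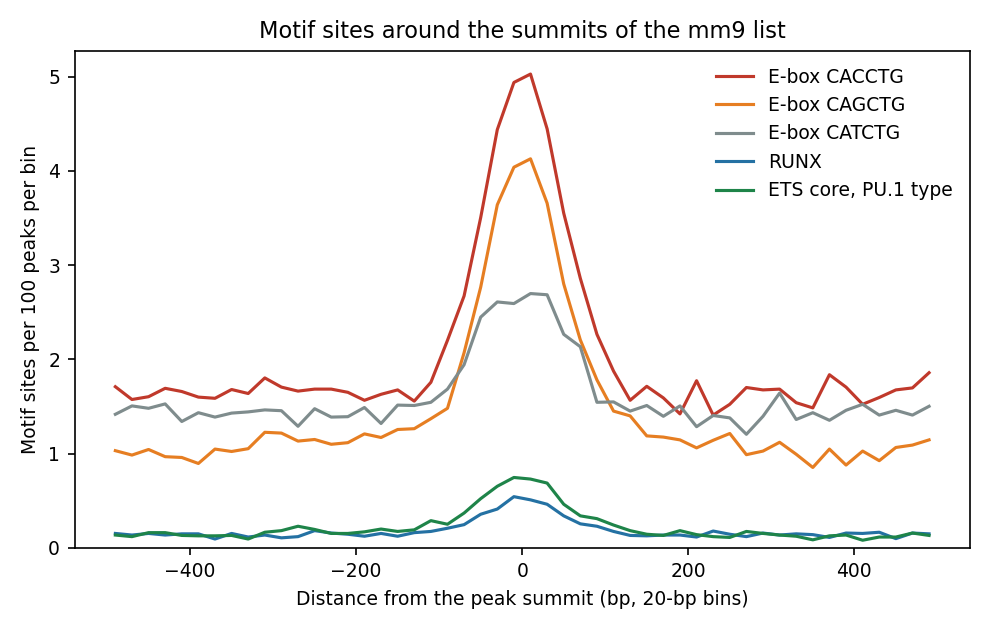
Motif sites per 100 peaks in 20-bp bins (vertical) by distance from the summit of mm9 peaks in bp (horizontal), 1 line per motif for CACCTG, CAGCTG, CATCTG, RUNX and the PU.1 type of ETS site. The lines of both main E-boxes peak at the summit, where the shares of peaks within 50 bp are 19.1% for CACCTG and 15.5% for CAGCTG.

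Genes of TCF12's own family and partners did not pass the planned test. Of the 18 measured genes for E proteins, ID proteins and their partners, 14 carried an optimal peak between 10 kb upstream and the 3' end. This was 77.8%, against a mean of 57.8% (33.3 to 77.8) in span-matched random lists (two-sided permutation p = 0.115, adjusted 0.191). The list passed the threshold in each replicate alone (88.9%, adjusted permutation p = 0.0120 in replicate 1; 83.3%, adjusted p = 0.0477 in replicate 2) and in the conservative list (adjusted permutation p = 0.00900). It did not pass at the stricter IDR (adjusted permutation p = 0.0557), by nearest 5' end (0.09999), within 5 kb (0.265) or with random lists matched also on weak relaxed peaks (adjusted p = 1). Cbfa2t3 had 12 peaks, Tcf4, the third E protein gene, had 25 with a strongest signal of 159, and Tcf3 had 6 with a strongest signal of 152. Tcf12 itself had 7 peaks, the strongest 78 bp downstream of its 5' end on mm10 chromosome 9 from 72111785 to 72111881, with a signal of 80.4. Runx1, a lymphoid and myeloid transcription factor gene, had 17 peaks with a strongest signal of 139. Id2 and Id3, genes of inhibitors that pair with E proteins and keep them off DNA, had their strongest peaks 11 bp and 7 bp from their 5' ends, with signals of 104 and 85.9. The strongest signals were 119 at the LIM-only gene Lmo4, 112 at the zinc finger gene Zeb2, 110 at Lyl1, 80.9 at Ldb1, 56.3 at Lmo2, 38.4 at Cbfa2t2 and 27.0 at Zeb1. Id1, Id4, Tal1 and Gfi1b had no optimal peak.

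Genes of B cell identity and of activated and germinal centre B cells carried peaks more often than genes of the same span. Peaks lay at 28 of 29 genes of B cell identity and B cell receptor signalling, 96.6% against 63.8% (44.8 to 79.3) in matched lists, and at all 26 genes of activated and germinal centre B cells, against 61.5% (42.3 to 80.8). Both had a two-sided permutation p of 0.0002, the smallest that 10000 random lists can give, and an adjusted p over the 15 lists of 0.000750. Pax5, the factor that keeps B cells committed, had 17 peaks, the strongest with a signal of 271, which 0.324% of optimal peaks exceeded. The Ikaros family gene Ikzf3 had 19 peaks (strongest 236), and the signalling adaptor gene Bank1 had 3 (217). Cd79b, a chain of the B cell receptor, and Cd74, the invariant chain of MHC class II, had peaks 7 bp and 11 bp upstream of their 5' ends, with signals of 209 and 189. Fcer2a, the low-affinity IgE receptor, was the only gene of the list without a peak. Among activated and germinal centre genes the strongest signals were 269 at Mef2b, 219 at Nfkb1, 205 at Nfkbia, 185 at Traf1 and 165 at Pim1. When random lists were matched also on the number of weak relaxed peaks in the gene window, neither list passed (adjusted permutation p = 0.0885 and 0.0520).

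Peaks also lay at 16 of 18 plasma cell genes, 88.9% against 60.6% (adjusted permutation p = 0.0350), among them Mzb1, a chaperone of antibody-secreting cells, with a signal of 369, Ell2 (264), Xbp1 (133), Prdm1 (122) and Jchain (120). Fkbp11 and Hspa5 had none. This call was lost in replicate 1 alone (adjusted permutation p = 0.117), within 5 kb of the 5' end (0.130) and with the added match on weak peaks (0.319). B-1 cell genes did not pass, at 14 of 15 genes (93.3% against 65.2%, adjusted permutation p = 0.0651), but did in replicate 2 alone (0.0105), in the conservative list (0.00900), within 5 kb (0.0473) and by nearest 5' end (0.0114). The B-1 genes with the strongest signals were Arid3a, Il10 (269), Bhlhe40 (169), Ctla4 (162) and Bhlhe41 (135), and Spn had no peak. Early B cell development genes did not pass either, at 13 of 17 (76.5% against 62.6%, adjusted permutation p = 0.416). Within that list Erg reached 200, Cnr2 190 and Lef1 182, and the surrogate light chain genes Igll1 and Vpreb1 had 2 peaks each and shared the strongest, with a signal of 177. Its summit lay at -6.76 kb and -1.49 kb of their 5' ends on the mm10 annotation. In the mm9 list the strongest peak of both, with a signal of 219, lay 0.092 kb downstream of the 5' end of Vpreb1. Rag1, Rag2, Kit and Cd93 had no optimal peak.

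Ribosomal protein and cell cycle genes, which dividing cells of any type use, also carried peaks more often. Each of the 39 cytoplasmic ribosomal protein genes had a peak, against 45.5% (30.8 to 61.5) in matched lists (permutation p = 0.0002, the smallest possible, adjusted 0.000750), with the strongest signals at Rps15 (239), Rpl10a (238), Rps6 (224), Rpl6 (211) and Rpl8 (208), all within 0.132 kb of the 5' end. It was the only list still called higher with the added match on weak peaks (adjusted permutation p = 0.00150). Cell cycle genes had peaks at 25 of 28, 89.3% against 61.4% (adjusted permutation p = 0.00840; 0.121 with the added match), led by E2f2 (190), Ccnd2 (145), Cdkn2c (108), Cdk6 (99.1) and Top2a (92.8). Ccnd1, Cdkn2a and Aurkb had none. Cell survival genes did not pass, at 24 of 29 (82.8% against 63.8%, adjusted permutation p = 0.0690), but did in each replicate alone (0.0116 and 0.0105), in the conservative list (0.0195), within 5 kb (0.0473) and by nearest 5' end (0.0439). Mcl1 (231), Bcl2l11 (205), Bcl2l1 (191), Tnfrsf13b (169) and Bid (163) had the strongest signals there.

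Liver genes carried peaks less often, at 5 of 25, or 20% against 59.5% (40 to 76; permutation p = 0.0002, the smallest possible, adjusted 0.000750). The 5 were Apoa2 (96.2), Fgb (57.8), G6pc (54.7), Pck1 (33.4) and F9 (21.4), while Alb, Apoa1, Apob and Apoc3 were among the 20 without. The lists for other cell types did not pass. T cell genes had peaks at 17 of 24 (70.8% against 64.7%, adjusted permutation p = 0.691), with signals of 208 at Lck and 158 at Ets1, and none at Cd8a, Cd8b1, Bcl11b or Zap70. Macrophage and granulocyte genes had peaks at 11 of 24 (45.8% against 55.7%, adjusted permutation p = 0.462), erythroid and megakaryocyte genes at 8 of 19 (42.1% against 56.0%, 0.395), skeletal muscle genes at 12 of 23 (52.2% against 58.2%, 0.691) and neuronal genes at 10 of 22 (45.5% against 63.1%, 0.199). The strongest signals in these lists were 88.7 at Itgam, 174 at the transferrin receptor gene Tfrc, 170 at Ryr1 and 97.3 at Gad1. Neuronal genes passed as lower in each replicate alone (31.8% in both, adjusted permutation p = 0.00900 and 0.00950), in the conservative list (0.00900) and at the stricter IDR (0.0114). Macrophage and granulocyte genes passed as lower within 5 kb (adjusted permutation p = 0.0473) and at the stricter IDR (0.0315), and erythroid genes within 5 kb (0.0445). Over all 20193 genes, 58.5% had a peak.

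**Figure D4:**
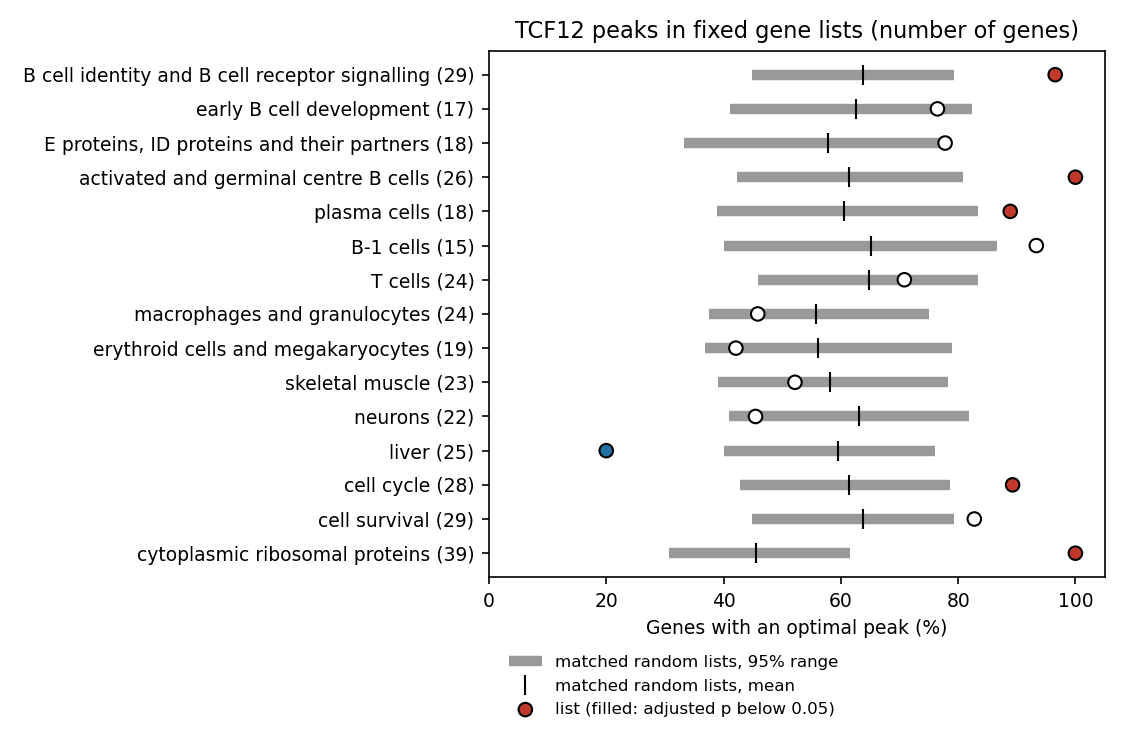
Percentage of genes with an optimal TCF12 peak from 10 kb upstream of the 5' end to the 3' end (horizontal) for the 15 gene lists (vertical), with the 95% range of 10000 span-matched random lists as bars and filled points at an adjusted p below 0.05. B cell identity (96.6%), activated and germinal centre (100%), plasma cell (88.9%), cell cycle (89.3%) and ribosomal protein genes (100%) lie above the matched lists, and liver genes (20%) lie below.

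The genes with the most peaks were long ones. Foxp1, a transcription factor gene needed for early B cells, had 57 peaks with a strongest signal of 150, and Gse1 had 41 (strongest 288). Prkca, a protein kinase C gene, had 40 (217), Septin9 had 39 (244) and Ebf1 had 34 (150). Peaks fell into 2225 groups of at least 4 summits no more than 12 kb apart, against a mean of 995 (range 946 to 1064) in 100 shuffles among the relaxed peaks of the same chromosome, and these groups held 39.1% of optimal peaks. The largest held 34 summits over 46.1 kb at Grap, Slc5a10 and Fam83g on mm10 chromosome 11, from 61638929 to 61685049. The next held 33 summits over 66.5 kb at Ubl7 and Sema7a on chromosome 9, from 57928956 to 57995468. The others of the 5 largest lay at Jade2 on chromosome 11 (26 summits, 51817996 to 51858052), at C1qtnf6, Sstr3, Rac2 and Cyth4 on chromosome 15 (26 summits, 78528579 to 78605506) and at Rnf157, Ubald2 and Qrich2 on chromosome 11 (24 summits, 116377406 to 116446178).

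Chromosome 11 held more TCF12 peaks than any other. It carried 32.4 optimal peaks per Mb, against a median of 13.5 (range 9.73 to 17.6) on the other autosomes, 2.40 times as many, and the ratio was 2.38 in replicate 1 and 2.47 in replicate 2. Weak relaxed peaks were in excess there too, at 234 per Mb against a median of 94.96 (77.7 to 162). Per protein-coding gene, chromosome 11 had 2.55 peaks against a median of 1.77 (1.09 to 2.73), within the range of the other autosomes. Chromosome X had 2.74 peaks per Mb, 0.190 times the autosomal density (Poisson interval 0.173 to 0.208), and the ratio was 0.127 for weak relaxed peaks. The share of peaks per chromosome in the mm9 list followed that in the mm10 list over 20 chromosomes, with Pearson's r of 0.998 and Spearman's rho of 0.995. Each of these 2 relations had a two-sided permutation p of 2e-05, the smallest that 100000 permutations can give where the smaller tail is doubled, and the same after adjustment over both, and r was 0.995 without the 2 chromosomes farthest from the median. Both lists came from the same 2 libraries.

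**Figure D5:**
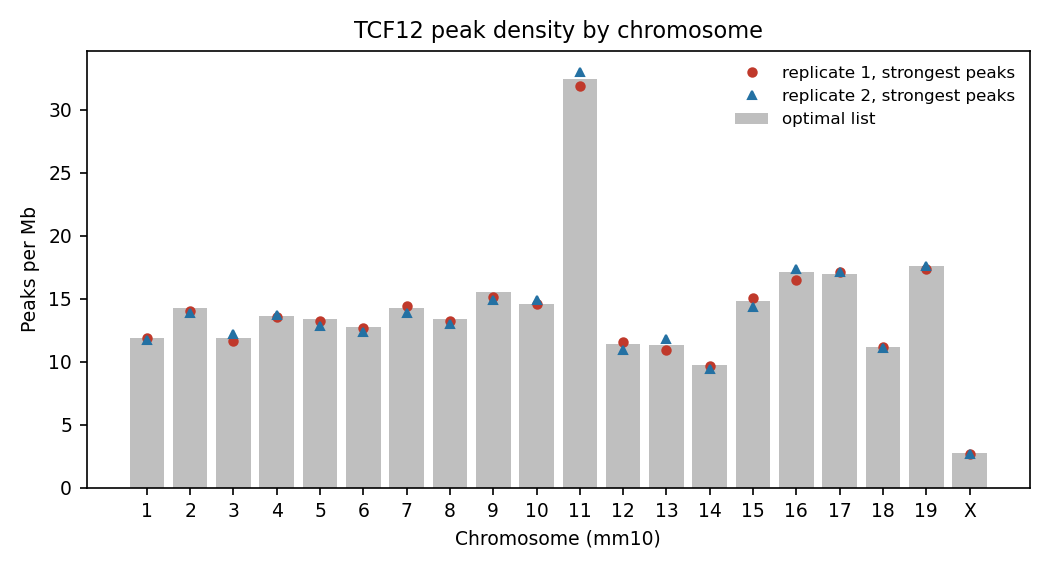
Optimal TCF12 peaks per Mb (vertical) by mm10 chromosome (horizontal), with the values of the strongest 35530 peaks of replicate 1 and replicate 2 as points. Chromosome 11 stands at 32.4 per Mb, the other autosomes lie between 9.73 and 17.6, and X is at 2.74.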

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

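The tests of weak or chance peaks, of signal with any antibody, of the cell cycle and ribosomal protein lists on their own, and the split of mm9 peaks by E-box and promoter other than E-box peaks outside promoters, were chosen only after the result was seen. The other tests were set before it. The design holds 1 group and so names no biological difference, and no biological explanation from the design was tested. The explanations weighed are features of the genome, the peaks and the signal, among them extra DNA copies, which alter read density without a change in binding.

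Peaks on sequences that the location, gene list and motif comparisons do not use numbered more than the 3 that a count of 0 allows in every mm10 list. Besides the optimal list, the conservative list held 9 peaks outside chromosomes 1 to 19 and X. The relaxed lists held 97 for the pooled data, 78 for replicate 1 and 115 for replicate 2. The peaks of the optimal list and those on chromosome Y were looked at. The optimal list held 12 peaks on 4 sequences not placed on a chromosome, with signals from 13.3 to 146. The relaxed list of replicate 2 held 4 peaks on chromosome Y, where the line is labelled female. Their highest signal, 2.89, lay below that list's median of 3.49 and near its minimum of 2.56, and the list holds background by design, so their number is not read as binding or as DNA of that chromosome. Replicate 1 and the optimal list had 0 there, and the mm9 list had 3.

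Promoter peaks held CAGCTG or CACCTG in 14.4% of cases and other peaks in 39.6%. Base composition was argued against, since the odds ratio pooled over strata of equal GC content was 0.256 (0.234 to 0.278). Summits placed too far from the site were argued against too: E-boxes in the ring 50 to 150 bp from promoter summits were 1.09 times (1.02 to 1.15) as frequent as around points 600 bp away, against 1.38 times for other peaks. Promoter peaks without an E-box were not weak, with a median signal 14.4 (13.03 to 15.6) above that of other peaks without one, 62.7 against 48.3. As 6919 of the 8085 promoter peaks held none, this largely repeats the median of all promoter peaks, 62.2. A high signal does not tell specific from unspecific signal, so nothing is concluded on chance peaks. Signal that collects at active promoters with any antibody stays open, since no other antibody or control library was analysed here. An E-box lay in 5.26% of 38 promoter peaks of ribosomal protein genes, 7.69% of 26 of germinal centre and 9.09% of 11 of plasma cell genes. It lay in 30.4% of 23 of B cell identity, 29.2% of 24 of cell cycle, 26.7% of 30 of cell survival and 35.7% of 14 of B-1 cell genes. The plasma cell share may leave out genes whose symbol is not in the mm9 annotation. These differences were not tested, so such signal may account for part of the promoter peaks.

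Chromosome 11 held 2.40 times as many optimal peaks per Mb as the median of the other autosomes. Gene density as the whole cause was argued against, because the ratio was still 1.76 (1.58 to 1.95) against 1-Mb bins of other autosomes with as many genes, and the same ratio ran from 0.704 to 1.33 for each of the others. Extra DNA copies of chromosome 11 in the line are a candidate explanation whose prediction was met. In 1-Mb bins with at most 2 genes, weak relaxed peaks were 1.98 times (1.38 to 2.66) as dense on chromosome 11 as on other autosomes, 87.0 against 44.0 per Mb, while single other autosomes reached 0.608 to 1.68. Only 25 such bins lie on chromosome 11, the lower bound lies within the range of the others, and copy number itself was not measured, so this remains a hypothesis. The density of weak peaks also need not follow copy number alone. The median signal of optimal peaks was not raised on chromosome 11, at 36.4 against a range of 33.3 to 37.7 on the other autosomes.

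The B cell identity, activated and germinal centre, plasma cell, cell cycle and ribosomal protein lists carried peaks more often than matched genes, 4 of the 5 also with all mm9 peaks (plasma cell adjusted permutation p = 0.0549). The mm9 annotation was searched by symbol alone and gave 16 plasma cell genes, against 18 measured on mm10. The missing plasma cell call may thus come from the genes measured and not from the mm9 peaks. Counting only mm9 peaks outside promoters with an E-box, 2 of the 5 were called, B cell identity (64.3% against 16.4%) and activated and germinal centre (38.5% against 10.8%), but peaks there without an E-box called the same 2 (71.4% against 22.1%, and 69.2% against 15.8%). Here an E-box means CAGCTG or CACCTG only. Of all peaks outside promoters without one, 15.4% held CATCTG and 8.78% held CACATG, so they are not free of every E-box. The bound set beforehand, that 1 such list would exclude peaks without an E-box at active genes as the cause, was therefore wrong, and that explanation stays open. For the cell cycle and ribosomal protein lists 0 of 2 were called with E-box peaks outside promoters (adjusted permutation p = 0.237 and 0.866); promoter peaks without an E-box called the ribosomal list (84.6% against 28.5%, adjusted permutation p = 0.00300) and not the cell cycle list (57.1% against 38.7%, 0.0952), which promoter peaks with an E-box called (25% against 7.45%, 0.0330). Promoter peaks without an E-box may thus lie behind the ribosomal call but stay open for both lists together, and no list was matched on expression. In these list tests a promoter peak lay within 1 kb of the 5' end of any protein-coding gene. A neighbouring gene's promoter inside the window of a listed gene therefore counted too.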

How the results depend on the processing

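The stronger 50% of the mm9 list, peaks in promoters alone, the GC-matched random positions and all alternatives for single motifs, gene body shares and the strength of named genes were chosen after seeing the data. Of the main results under their alternatives, 26 kept their direction and their side of the threshold, lay within their error or, for counts, within a set factor. Another 23 moved and 1 reversed, and the cause was not tested where none is named. A count within that factor can still differ: the 35836 optimal peaks on chromosomes 1 to 19 and X became 24282 at an IDR of 0.01 or less. The conservative share went from 83.6% to 79.6% with a reciprocal overlap of 50% and to 95.03% at an IDR of 0.01 or less. The replicate overlap went from 73.5% to 65.8% with a reciprocal overlap, 61.1% for summits within 100 bp, 76.1% and 61.4% with N/2 and 2N strongest peaks, and 72.7% counted from replicate 2. The rank correlation of 0.697 was 0.710 as Pearson's r of log2 signal, 0.734 in the conservative list, and 0.538 among the 5000 strongest and 0.539 outside them, where the range of signal is narrower by construction. A minimum of 6 summits left 959 of 2225 groups, which it must lower. The promoter share of 28.9% was 24.2% at 500 bp, 35.4% at 2.5 kb, 29.5% in the conservative list, 33.6% at the stricter IDR and 28.4% to 28.7% without either replicate. The number of lists called higher went from 5 to 1 with matching on weak relaxed peaks, to 8 in the conservative list and to 6 to 8 without either replicate. The intron share of 30.4% was 31.8% and 27.8% at the shorter and longer promoter distance, and 27.3% in the stronger 50%. The E-box difference between the strongest and weakest of 5 groups by signal, 9.74 points, turned to -3.09 in promoters. The E-box ratio of 2.55 ran from 1.72 against GC-matched random positions to 2.91 with a window of 25 bp, and the X to autosome ratio from 0.173 to 0.205. Among single gene lists 80 comparisons were the same, 6 lost and 19 gained a call, and among single motifs 88 were the same, 2 lost and 6 gained one. For the intron share, the E-box ratio and the E-box share by signal, the conservative list, the stricter IDR, each replicate alone and a background of GC-matched relaxed peaks were not run, since they need mm10 sequence or exons. No paired analysis was possible because there is 1 group. Read depth is unknown, so weak peaks missing from a replicate are not shown to be absent.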

Other observations

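The gene list tests on mm9 peaks and the values on neighbouring motifs and 6-mers were chosen after seeing the data, although the test of E-box peaks outside promoters was set before its own result was seen. With all mm9 peaks, lists that had not passed on mm10 did so: B-1 cells (93.3% against 56.9%, adjusted permutation p = 0.0168) and cell survival (89.3% against 55.8%, 0.000750) as higher, and macrophages and granulocytes (18.2% against 45.0%, 0.0197) and neurons (27.3% against 56.1%, 0.0197) as lower. Liver, lower on mm10, was lower here too (24% against 50.3%, adjusted permutation p = 0.0199). Genes were found by symbol alone in these mm9 tests, so some lists held fewer genes than on mm10. For macrophages and granulocytes, 22 genes were measured against 24. Outside promoters, peaks with an E-box lay at more genes of 6 lists than at span-matched genes. Besides the B cell identity and germinal centre lists, these were early B cell development (10 of 17 genes, 58.8% against 15.5%, adjusted permutation p = 0.00150), E proteins, ID proteins and their partners (10 of 18, 55.6% against 15.9%, 0.00200), B-1 cells (7 of 15, 46.7% against 13.1%, 0.00660) and cell survival (9 of 28, 32.1% against 12.4%, 0.0230). Peaks outside promoters without an E-box called 4 lists: B cell identity (71.4% against 22.1%, adjusted permutation p = 0.000750), activated and germinal centre (69.2% against 15.8%, 0.000750), B-1 cells (80% against 18.8%, 0.000750) and cell survival (64.3% against 17.9%, 0.000750). They did not call early B cell development (41.2% against 21.4%, adjusted permutation p = 0.163) or the E protein list (44.4% against 21.3%, 0.0705), and the difference between both kinds of peak was not tested. Cbfa2t3 had an E-box in 6 of its 7 mm9 peaks, Bcl2l1, an anti-apoptotic gene, in 7 of 12, Tcf3 in 3 of 4 and Pax5 in 7 of 14, promoter peaks included, while Ikzf3 had it in 3 of 14, Tcf4 in 3 of 13, Lef1 in 1 of 8 and Traf1 and Bhlhe40 in 1 of 7 each. The strongest Bcl2l1 peak lay in an intron on mm9 chromosome 2 from 152642089 to 152642388 and held CACCTG in GAAATCTGCACCTGCTCTTGCT at 152642220 to 152642225. The strongest Ets1 peak, in an intron 112 kb from its 5' end, held CACCTG in GGCAGAGACACCTGGCTGGAAG at mm9 chromosome 9, 32555454 to 32555459. Promoter peaks with an E-box called B cell identity (25% against 7.05%), B-1 cells (33.3% against 7.69%), cell cycle (25% against 7.45%) and cell survival (25% against 7.68%), each with an adjusted permutation p of 0.0330. Genes with a promoter peak of any kind in their window were less frequent than among matched genes in all 6 lists of other cell types: neurons (1 of 22 genes, 4.55% against 41.7%, adjusted permutation p = 0.00150), liver (12.0% against 41.5%, 0.00780), erythroid cells (5.88% against 39.9%, 0.00900), macrophages and granulocytes (9.09% against 36.7%, 0.00937), skeletal muscle (17.4% against 41.3%, 0.0366) and T cells (20.8% against 43.6%, 0.0450). Promoters of neighbouring genes inside the window counted in these shares. The strongest mm9 peak of the neuronal gene Slc17a7, for example, was a promoter peak at -9.62 kb of its 5' end.

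Outside promoters, peaks with CAGCTG or CACCTG held some other motifs less often than peaks without them. SP/KLF sites lay in 4.29% against 7.56% (odds ratio 0.548, Fisher's exact test, adjusted p over 30 motifs 1.51e-15), YY1 sites in 0.619% against 1.38% (0.445, adjusted p = 7.04e-05), PU.1-type ETS sites in 3.13% against 4.46% (0.692, adjusted p = 0.000236) and AP-1 sites in 8.44% against 9.79% (0.850, adjusted p = 0.0166). For RUNX, EBF1, NF-kappaB and octamer sites no difference passed the threshold (adjusted exact p = 0.904, 0.588, 0.904 and 0.1497). Among 2075 6-mers ranked by their ratio of summit to flank, the ETS-like CCGGAA came in place 1 (3.75), CAGCTG in place 4 (3.08) and CACCTG in place 12 (2.52). This ranking took promoter peaks and other peaks together and was not corrected for base composition, so it does not rank the motifs as sites of TCF12.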
